A study of Mus musculus with 2 samples.

How the data were processed

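Single-cell RNA sequencing was done on mouse mammary cells sorted as negative for Ter119, CD31 and CD45, taken at 18.5 days of pregnancy. There was 1 library of Ehf knockout cells and 1 of wild type cells, and each library pooled the glands of 2 females, per the labels' protocols. Libraries were made with the 10x Chromium 3' chemistry, which counts the 3' ends of transcripts with unique molecular identifiers (UMIs). The deposited matrices hold whole-number UMI counts per gene and barcode with no normalization. The submitters' processing notes name the GRCm38 (mm10) build and Seurat 4.0.4; the aligner, the counting tool and the rule by which barcodes were kept are not given in the sources used here. Every deposited barcode held at least 500 UMIs. Both matrices list the same 27179 features, of which 1314 carry no gene symbol and hold 1.74% of the knockout and 1.36% of the wild type UMIs. The features and barcodes files hold names and no measurement.

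Cells were kept with at least 500 detected genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 6%. It called 122 of 9211 wild type cells at a score threshold of 0.379, and 0 of 6561 knockout cells at 0.621, so its automatic threshold did not work in the knockout library. At the wild type threshold 38 knockout cells (0.579%) would be called, of which 14 were luminal secretory, 18 basal and 6 hormone-sensing. These were kept, and left out in an alternative added after seeing the data. This left 6561 knockout and 9089 wild type cells.

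Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components and 20 neighbours entered Leiden clustering at resolution 1 (leidenalg 0.10.2, seed 1). Milk protein, milk lipid, mitochondrial and ribosomal protein genes were left out of clustering, so that these genes did not make the clusters. The 19 clusters were named from fixed markers by the highest median log2 fold over all other cells, with 5 CPM added, a median of at least 0.3 and at least 3 detected markers. The alveolar markers included milk genes such as Wap, Lalba and the caseins, and the luminal progenitor markers included Hp. Names of clusters were thus not independent of the genes compared. Alveolar-like and luminal progenitor-like clusters were joined as 1 luminal secretory class. In every cluster the top 10 genes against other classes held at least as many markers of its own class as of any other.

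UMIs were summed per library and class, and levels were scaled so that the median log2 ratio over genes with at least 50 UMIs over both libraries was 0. Levels are given as scaled CPM, and plain scaling means CPM of all UMIs of the class. Log2 ratios are knockout over wild type. With 1 library per genotype no test was possible and none was run. Sums carry exact Poisson intervals, ratios exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95% and covering counting error only. They say nothing of the spread between animals. Zero counts were set at 3 counts for a bound. Of 32 gene lists, each with at least 3 measured members was given as the median of its members, with its percentile among 10000 random lists matched on mean level in 20 bins, as a description of these libraries. A member was called higher or lower at a 1.5-fold difference, a rule of size.

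Named genes followed a rule fixed before the data were examined. In luminal secretory cells these were the 12 highest and 12 lowest ratios among genes with a level of at least 50 CPM in the higher library, at least 200 UMIs over both libraries and the same direction under all 3 scalings. Predicted genes and mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes were left out. In basal and hormone-sensing cells they were the 6 highest and 6 lowest, leaving out milk protein genes. The rule also took Ehf, up to 4 members of each list described by size of ratio, and the measured milk protein and prolactin, Stat5 and Elf5 list members. Some genes that the rule took are not reported here.

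For shares per cell, each cell was thinned to 2000 UMIs and shallower cells were left out. A cycling cell had at least 3 UMIs of 8 cell cycle genes (Mki67, Top2a, Cdk1, Ccnb1, Birc5, Cenpf, Nusap1 and Ube2c). The level step was tested on simulated counts drawn from the real gene means and depths with 200 changed genes. Among the 11380 luminal secretory genes, simulated 2-fold changes came back at a median log2 of 0.99, and the intervals held the true value for 95.5% of genes. Both simulated libraries were Poisson draws from a pooled profile, with changes in both directions. No large shift of composition such as that of milk genes, and no spread between cells, was simulated, so this checks only the counting step. Alternatives set beforehand covered scaling, gene filter, weight of cells, free RNA, cell filter, doublets, clustering, thinning and the cycling minimum, and 4 more were added after seeing the data. For free RNA, the summed profile of a library's non-epithelial cells, their own transcripts included, was subtracted from each class. Its share was set by the milk protein gene with the lowest basal over non-epithelial ratio. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. The position of Ehf came from GENCODE release 21 for mouse on GRCm38.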

Results

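Mammary cells of late pregnant mice with and without Ehf, an ETS family transcription factor of epithelial cells, were profiled by single-cell RNA sequencing. The design asks what the loss of Ehf does to the epithelium at 18.5 days of pregnancy, when alveolar cells prepare for milk secretion. The knockout library held 7275 barcodes and 40066795 UMIs, with a median of 3707 UMIs and 1574 genes per barcode. The wild type library held 11258 barcodes and 48720938 UMIs, with a median of 2163.5 UMIs and 1055 genes. After filtering, medians were 3900 and 2481 UMIs per cell. There was 1 library per genotype, so no difference below has a replicate check, and intervals cover counting error only.

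Ehf, on chromosome 2 from 103263433 to 103303278 on the minus strand of GRCm38, was lower in luminal secretory and basal cells of the knockout library but was not absent from them. In luminal secretory cells it had 1077 UMIs in the knockout and 3341 in the wild type, a scaled level of 59.9 against 154 CPM and a log2 ratio of -1.37 (-1.47 to -1.27). That ratio was -0.51 on plain scaling, -2.38 with free RNA subtracted and -2.11 within cluster 8. In basal cells 81 and 162 UMIs gave -1.71 (-2.11 to -1.31). Levels there were 3.34 and 10.9 scaled CPM, far below those of luminal secretory cells, so free RNA is open for this ratio. Subtraction of free RNA, which is not a clean correction, cannot settle it. In hormone-sensing cells 28 and 22 UMIs gave -0.60 with an interval that included 0 (-1.46 to 0.27), so no difference was detectable there at this depth. At least 1 Ehf UMI was seen in 54.8% of knockout and 57.5% of wild type luminal secretory cells, against 1.40% and 2.46% of basal cells, at median depths of 10558, 9000, 3682 and 2042 UMIs in the same order. Thinned to 2000 UMIs, which left out 27, 104, 193 and 2943 cells, these shares were 14.7%, 21.2%, 0.713% and 2.20%. In hormone-sensing cells the shares were 13.9% in the knockout and 10.3% in the wild type, or 4.70% and 4.88% after thinning. The deleted part of the gene is not given in the sources used here, and a 3' tag outside it, as in the last of the 9 exons (103263433 to 103266871), checks nothing.

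Luminal secretory cells, which make milk, were a smaller part of the knockout library. They were 12.5% of kept cells (823 of 6561, 11.8 to 13.4%) in the knockout and 28.2% (2559 of 9089, 27.2 to 29.1%) in the wild type. Basal cells, the contractile outer layer, were 84.1% against 68.4%, hormone-sensing cells 2.30% against 1.39%, and non-epithelial cells 1.04% against 2.02%. The sort, the UMI minimum and the depth gap between libraries can all set these shares. The filter left out 714 knockout and 2169 wild type barcodes, called doublets included.

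**Figure D1:**
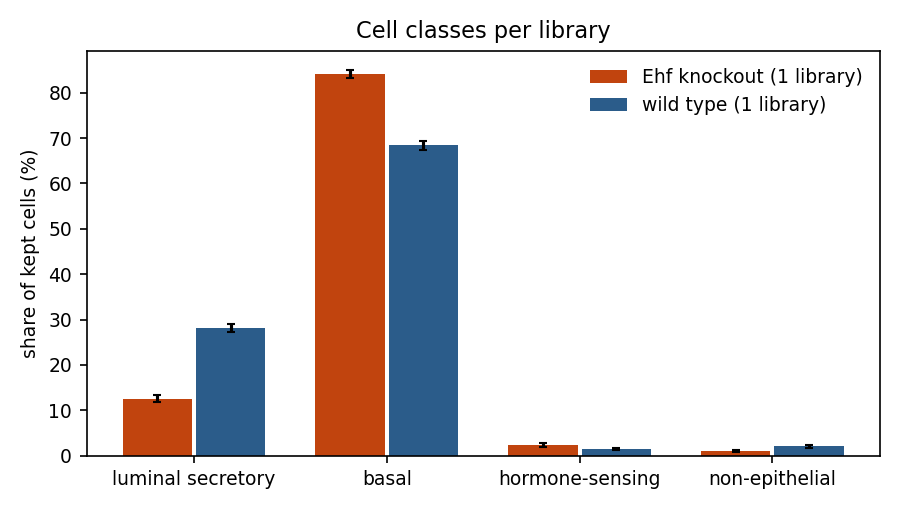
Share of kept cells (%) in each class for the knockout and wild type libraries, 1 library each; bars are shares and lines are exact 95% intervals for counting error. Luminal secretory cells were 12.5% of the knockout and 28.2% of the wild type library.

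In luminal secretory cells, genes of milk production were far lower in the knockout library. All 12 measured milk protein genes were at least 1.5-fold lower, with a median log2 ratio of -3.14, below every one of 10000 matched random lists. This median was -2.28 on plain scaling and -4.09 with free RNA subtracted. Milk protein genes made up 10.3% of this class's UMIs in the knockout and 38.9% in the wild type. Plain scaling put the median of all genes at 0.86 and scaling outside milk genes put it at 0.31. Milk protein UMIs thus account for only part of this shift, and the cause of the rest was not tested. Ratios here are relative to the median of all genes. Different clusters held most of the class in each library, and this limits the comparison. Knockout cells lay mostly in the luminal progenitor-like cluster 8 (51.5%) and the alveolar-like cluster 7 (32.6%), wild type cells in the alveolar-like clusters 4 (46.3%) and 5 (35.4%). Milk genes were among the markers that gave these names, so the names partly restate milk gene levels. Clusters were compared within themselves where they held at least 50 cells of each library. Cluster 4 held 18 knockout cells and was not compared, so much of the wild type class has no value within a cluster. The milk protein median was -3.19 in cluster 7, -0.88 in cluster 5 and -0.22 in cluster 8. Of the 12 genes, 11 were lower and 0 higher in cluster 7, 7 lower and 1 higher in cluster 5, and 6 lower and 5 higher in cluster 8. In cluster 5 basal markers (median 0.64, 8 of 11 higher and 1 lower) and mesenchymal genes (1.48, 3 of 3 higher) were also higher in the knockout library. At the wild type doublet score threshold 0 of 113 knockout cells of cluster 5 and 14 of 424 of cluster 8 would be called doublets. Basal markers in cluster 5 lay at a median of 1.91% of their level in knockout basal cells. With 1 library per group, a cluster mostly of 1 library may be that library and not a type. Of the list medians and genes taken by the naming rule that differed at least 1.5-fold in the class, 0 reversed within cluster 7, 9 within cluster 5 and 51 within cluster 8.

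Among milk proteins, Glycam1 was at 679 against 67972 scaled CPM, a log2 ratio of -6.65, and Spp1 (osteopontin) at -5.66. Lalba, the lactose synthase subunit alpha-lactalbumin, was at -4.96 and Wap, whey acidic protein, at -4.57. With no cell filter Glycam1 was at -5.74, Spp1 at -4.90, Lalba at -4.08 and Wap at -3.70. With free RNA subtracted they were at -7.66, -6.69, -6.00 and -5.57 in the same order. Most of that move was a shift shared by many genes of the class. Ehf, for example, went from -1.37 to -2.38, so the move is not particular to milk genes. The caseins lay at -3.82 for Csn1s1, -2.91 for Csn1s2b, -2.64 for Csn1s2a, -2.51 for Csn2 and -2.24 for Csn3. Mfge8 was at -3.36, Trf (transferrin) at -2.47 and Wfdc18 at -0.69, of which Wfdc18 was at 0.17 on plain scaling. Within cluster 8, Glycam1 (-3.30), Mfge8 (-3.13), Spp1 (-2.16), Wap (-0.81), Csn1s1 (-0.63) and Lalba were lower in the knockout library too. Csn1s2a (1.52), Csn3 (1.04), Csn2 (1.00), Trf (0.72) and Wfdc18 (0.18) were instead higher there, as was Wfdc18 in cluster 5 (0.70), while the interval of Csn1s2b (0.78) in cluster 8 included 0.

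**Figure D2:**
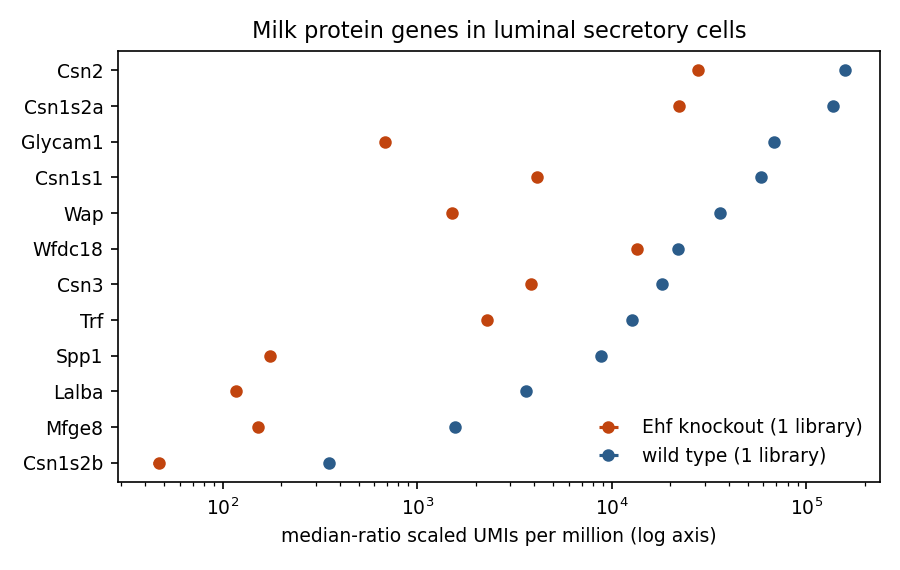
Median-ratio scaled CPM (log axis) of the 12 milk protein genes in luminal secretory cells, 1 library per genotype; points are levels and lines exact 95% Poisson intervals, mostly narrower than the points. Every gene lies lower in the knockout, Wfdc18 least at a log2 ratio of -0.69, which is 0.17 on plain scaling.

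Milk lipid genes followed. Of 30 measured members 27 were lower and 1 higher, with a median of -2.20, or -1.34 on plain scaling. Cidea, a lipid droplet protein, had 81 against 10558 UMIs, a 108-fold lower level. Lpl (lipoprotein lipase) was at -3.48, Fabp3 (a fatty acid binding protein) at -3.16 and Btn1a1 (butyrophilin of the milk fat globule) at -3.10. This list's median was -3.11 with free RNA subtracted, and -0.63 in cluster 5, -1.81 in cluster 7 and 0.73 in cluster 8, where Lpl and Fabp3 were both at 1.10. Genes of lactose synthesis and transport had a median of -1.03, with 17 of 25 lower and 3 higher, but that median was -0.17 on plain scaling. The calcium pump gene Atp2b2 (-6.11, or -4.45 thinned before summing), the phosphate carrier gene Slc34a2 (-5.09), Slc39a8 (-3.42) and Atp2c2 (-3.39) differed most. The list's median was -1.64 with free RNA subtracted, and -0.55 in cluster 5, -0.91 in cluster 7 and 0.34 in cluster 8, and Atp2c2, with 2 wild type UMIs in cluster 8, was at 1.64 (-0.28 to 4.72). Cholesterol synthesis genes had a median of -0.94, with 15 of 19 lower, including Hsd17b7 at -2.19, Msmo1 at -1.43 (-0.23 with free RNA subtracted) and Lss at -1.35. Their median was -0.08 on plain scaling. It was -0.80 in cluster 5, with 9 of 17 lower, -0.80 in cluster 7, with 14 of 19 lower, and 0.22 in cluster 8, where Msmo1 (0.39) and Hsd17b7 (0.01) had intervals that included 0.

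The remaining lowest genes by the fixed rule were Sftpd (surfactant protein D, -4.71), Lao1 (an L-amino acid oxidase, -4.43), Cxcl2 (a neutrophil chemokine, -4.04), S100a8 (-3.90) and Dab2 (-3.69). In cluster 8 the ratios of Lao1 (0.24) and Dab2 (0.45) had intervals that included 0. Mucosal defence genes had a median of -1.28, or -0.42 on plain scaling, with 13 of 16 lower. Ltf (lactoferrin) was at -2.82, Pigr (the polymeric immunoglobulin receptor) at -2.69 and Lpo (lactoperoxidase) at -2.57. The list's median was -2.14 with free RNA subtracted, and -0.46 in cluster 5, -1.14 in cluster 7 and -0.09 in cluster 8, where Pigr was at 0.92. Hp (haptoglobin) went the other way, with 806 UMIs in the knockout and 4 in the wild type, a ratio of 7.92 (6.56 to 9.80). It was seen in 18.5% of knockout and 0.156% of wild type luminal secretory cells, against 0.381% and 0.0161% of basal cells, at the depths given for Ehf. Thinned to 2000 UMIs, the luminal secretory shares were 7.54% and 0.0407%. Hormone-sensing cells also had Hp, in 45.0% of knockout and 40.5% of wild type cells, or 21.5% and 23.6% after thinning. Within cluster 7 the ratio of Hp was 8.48 (5.99 to 13.78), with 1 wild type UMI, and within cluster 8, with 0 wild type UMIs, it was at least 2.80. The inflammatory list had a median of -0.59 and 10 of 20 members lower, led by Cxcl2, Saa2 (-2.86), Saa1 (-2.64) and Cxcl1 (-2.47), but its median was 0.27 on plain scaling. Saa2 and Saa1 were at -4.05 and -3.71 with equal weight per cell and at -3.79 and -4.17 thinned before summing. With no cell filter they were at -1.89 and -1.73.

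Genes of DNA replication and division were higher in the knockout library. The proliferation list had a median of 0.98, with 27 of 30 members higher and 0 lower. Mcm7 (2.15), Mcm3 (2.07) and Mcm5 (1.87), parts of the replicative helicase, and Hmgb2 (1.58) led it, and the DNA ligase gene Lig1 was at 1.87. The list's median was 0.17 with no cell filter and 1.61 with free RNA subtracted. Thinned to 2000 UMIs, 20.9% of 796 knockout cells (18.1 to 23.8%) and 5.66% of 2455 wild type cells (4.78 to 6.65%) were cycling, leaving out 27 and 104 shallower cells. At that depth milk protein genes took a median of 5.53% of UMIs per knockout and 38.3% per wild type cell. Wild type cells thus had fewer UMIs left for cell cycle genes, which can widen the gap. No share was computed on UMIs outside milk genes. Without thinning the cycling shares were 43.7% and 17.7%. They were 11.1% and 1.99% thinned to 1000 UMIs and 10.4% and 2.40% at a minimum of 5 cell cycle UMIs, and at a minimum of 2 the wild type share was 9.45%. With no cell filter they were 4.36% and 1.27%, in a class that then held 614 knockout and 2658 wild type cells, while 299 knockout (4.11%) and 257 wild type cells (2.31%) lay in clusters without a name. Within clusters the list's median was nearer 0, at 0.25 in cluster 5, 0.18 in cluster 7 and 0.47 in cluster 8, where Mcm3 was at -0.08 with an interval that included 0.

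The other highest genes by the fixed rule were Tnfaip2 (2.80), Derl3 (a protein of endoplasmic reticulum degradation, 2.48), Clca3a2 (2.07), Tagln2 (2.03), Ccnd1 (cyclin D1, 2.01), Rspo1 (a Wnt pathway agonist, 1.98), Anxa2 (1.97), Lgals7 (1.90), Wfdc12 (1.79) and S100a6 (1.74). With free RNA subtracted Derl3 was at 1.62, Rspo1 at 1.11 and Wfdc12 at 1.04, the other 7 gave no value, and with no cell filter Wfdc12 was at 0.32. Within cluster 8, Tnfaip2 (-0.43), Clca3a2 (-0.61), Tagln2 (-1.09), Anxa2 (-1.50) and S100a6 (-1.12) were lower in the knockout library, and within cluster 5 so were S100a6 (-1.89) and Wfdc12 (-1.93), while the interval of Anxa2 (-0.41) included 0 there. The unfolded protein response list had a median of 0.41, with 8 of 20 higher and 3 lower, including Creld2 (1.68), Sdf2l1 (1.35), Xbp1 (-1.37) and Asns (-1.02). Within clusters 7 and 8 the list's median was 0.65 and 1.46, with Xbp1 at 0.94 and Asns at 1.28 in cluster 8. In cluster 5 it was 0.00 and the interval of Xbp1 (0.12) included 0. The breast tumour gene list had a median of 0.70 with 12 of 23 higher and 0 lower, led by Ccnd1, Brca2 (1.88), Brca1 (1.27) and Trp53 (1.18). Its median was 0.58 within cluster 7, with 10 of 20 higher and 1 lower, -0.16 within cluster 5 and -0.61 within cluster 8, where the interval of Trp53 (-0.25) included 0, and -0.34 after free RNA was subtracted.

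Regulators of prolactin signalling differed less than the milk genes. Of 20 measured members of the prolactin, Stat5 and Elf5 list 8 were lower and 3 higher, with a median of -0.33, or 0.53 on plain scaling and -0.97 with free RNA subtracted. Besides Ccnd1, the higher members were Igf1r (0.96) and Socs2 (0.59). Tnfrsf11a was at -1.31, Irs1 at -1.25, Nr3c1 (the glucocorticoid receptor) at -1.20, Socs3 at -1.07, Prlr (the prolactin receptor) at -1.05, Akt1 at -0.96, Elf5 at -0.84 and Gata3 at -0.71. Elf5 was at 0.02 and Gata3 at 0.15 on plain scaling. With free RNA subtracted Prlr was at -2.03, Elf5 at -1.85, Gata3 at -1.51, Stat5a at -1.24, Cish at -1.19, Irs1 at -0.29, Nfib at 0.86 and Tfap2c at 0.92, and thinned before summing Socs3 was at -0.45. Within clusters the list's median was 0.20 in cluster 5, -0.37 in cluster 7 and 0.09 in cluster 8. Elf5 was higher in the knockout library in clusters 5 (0.17) and 8 (0.87) and Igf1r lower in cluster 8 (-1.51), while the intervals of Prlr (0.50) in cluster 8 and of Tnfrsf11a in clusters 5 (0.23) and 8 (0.40) included 0. Stat5a (-0.36), Stat5b (-0.30), Cish (-0.57), Socs1 (0.41), Cebpb (0.28), Nfib (-0.27), Jak2 (0.25), Tfap2c (-0.22) and Id2 (0.00) lay within 1.5-fold, and each of these with a ratio below 0 was above 0 on plain scaling.

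Milk protein shares also differed cell by cell. Milk protein genes gave a median of 5.53% of UMIs per knockout luminal secretory cell (quartiles 2.60 and 12.4%) and 38.3% per wild type cell (29.1 and 45.8%), after thinning to 2000 UMIs. Without thinning the medians were 5.46% and 37.8%. Milk protein genes exceeded 25% of UMIs in 7.29% of knockout and 82.0% of wild type cells. Of all UMIs within a cluster, milk protein genes took 8.75% in the knockout and 36.9% in the wild type in cluster 7, 21.9% and 30.7% in cluster 5, and 7.75% and 5.10% in cluster 8, where the knockout share was the higher. In basal cells the medians were 0.20% and 1.05%. This share is not a pure measure of background, since the list member Mfge8 was seen in 79.3% of knockout and 73.2% of wild type basal cells. In the knockout library Mfge8 was at 507 scaled CPM in basal and 152 in luminal secretory cells.

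**Figure D3:**
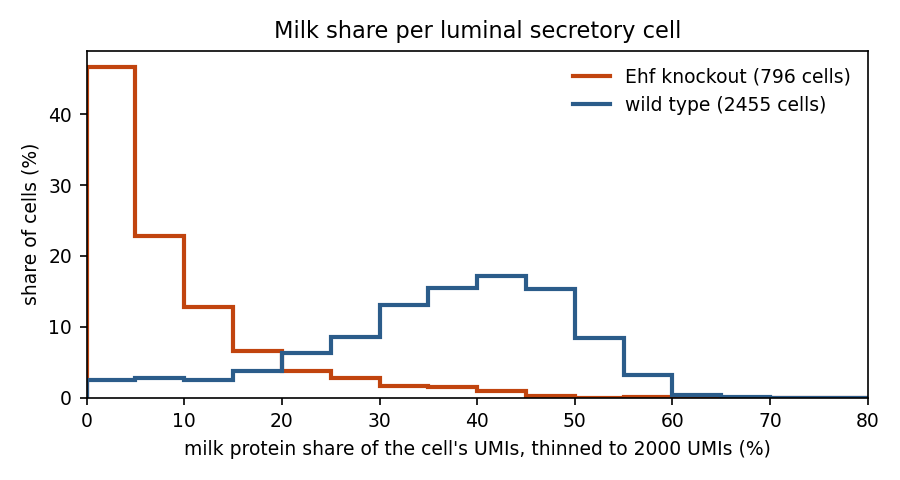
Distribution of the milk protein share of UMIs (%) over luminal secretory cells thinned to 2000 UMIs, as the share of cells in bins 5 percentage points wide. The medians were 5.53% over 796 knockout cells and 38.3% over 2455 wild type cells.

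Basal cells, 5519 in the knockout and 6220 in the wild type library, differed less, and plain scaling put the median of all their genes at -0.01. Higher in the knockout library were Ppp1r14b (a phosphatase inhibitor, 1.97), Wif1 (a secreted Wnt inhibitor, 1.65), Pappa (a protease of insulin-like growth factor binding proteins, 1.62), Fbln2 (fibulin 2, 1.47), Cebpb (a transcription factor, 1.42) and Chil1 (1.40). Lower were Lao1 (-4.92), Fabp3 (-3.08), Scd1 (a fatty acid desaturase, -1.58), S100a6 (-1.58), Itga1 (integrin alpha 1, -1.44) and Rn18s, a ribosomal RNA (-1.34). Lao1, Fabp3 and Scd1 had higher levels in wild type luminal secretory cells (2018, 7730 and 1375 scaled CPM) than in wild type basal cells (58.9, 248 and 79.0), and free RNA is open for all of them. With free RNA subtracted they were at -4.96, -1.62 and -0.82, Pappa was at 0.81, Chil1 at 0.59 and S100a6 at -2.21, and Ppp1r14b and Fbln2 gave no value. The basal marker list had a median of -0.36, or -1.09 with free RNA subtracted, with 2 of 14 lower, including Oxtr, the oxytocin receptor (-1.07), and Myh11, a smooth muscle myosin (-0.68), which were at -1.82 and -1.41 with free RNA subtracted. Interferon genes had a median of -0.41 with 6 of 18 lower, led by Ifit1 (-1.39), Usp18 (-1.21) and Oasl2 (-1.09). Cholesterol synthesis genes had a median of -0.46 with 4 of 19 lower, including Msmo1 (-0.97) and Fdps (-0.91). Most knockout basal cells lay in clusters 1 (42.3%) and 3 (31.8%), most wild type ones in clusters 0 (47.8%) and 2 (28.6%). Within clusters 0, 1, 2 and 3 the basal list's median was -0.13, -0.10, 0.06 and -0.19, that of interferon genes -0.05, -0.43, -0.32 and -0.45, and that of cholesterol genes -0.12, -0.27, -0.11 and 0.08. Cycling basal cells were 2.61% in the knockout and 5.49% in the wild type library after thinning, which left out 193 and 2943 shallower cells, but 3.35% and 3.36% without thinning.

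Hormone-sensing cells, 151 in the knockout and 126 in the wild type library, were the smallest epithelial class. Higher in the knockout library were Defb1 (a beta defensin, 3.28), Pnmt (3.21), Id3 (2.51), Lrrc17 (2.24), Tubb2b (1.93) and Calca (calcitonin, 1.70). Within the hormone-sensing list Areg, the growth factor amphiregulin (1.59), and Tnfsf11, the RANK ligand (1.47), were also higher, while the list median was -0.15. With free RNA subtracted Defb1 was at 2.57, Pnmt at 2.48, Tubb2b at 1.30, Calca at 0.98, Areg at 0.88, Tnfsf11 at 0.74 and the list median at -0.87, and Id3 and Lrrc17 gave no value. Lower were Fabp3 (-5.30), Prss23 (-2.17), Rn18s (-1.21), Ctsl (cathepsin L, -1.28), Fxyd2 (-1.19) and Clu (-1.17). The same subtraction put Rn18s at 4.88, Fabp3 at -6.68 and Fxyd2 at -1.91, and Clu was at -1.75, or -1.94 with 1 doublet score threshold for both libraries. Free RNA is also open for Fabp3, which had 579 scaled CPM in wild type hormone-sensing cells against 7730 in wild type luminal secretory cells. Cholesterol synthesis genes had a median of -0.83 with 8 of 11 lower, including Msmo1 (-1.50) and Cyp51 (-0.95). Basal marker genes had a median of -0.78 in these cells, with 6 of 9 lower and 1 higher, led by Krt5 (-1.48) and Myh11 (-1.29). Cycling cells were 1 of 149 knockout and 6 of 123 wild type cells after thinning, which left out 2 and 3 cells, and 3 of 151 and 7 of 126 without it. Pnmt was seen in 46.4% of knockout and 6.35% of wild type hormone-sensing cells, against 0.0544% and 0.0161% of basal cells, and in 21.5% and 3.25% of hormone-sensing cells after thinning. The median depths were 7784 and 4403.5 UMIs in hormone-sensing and 3682 and 2042 UMIs in basal cells.

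**Figure D4:**
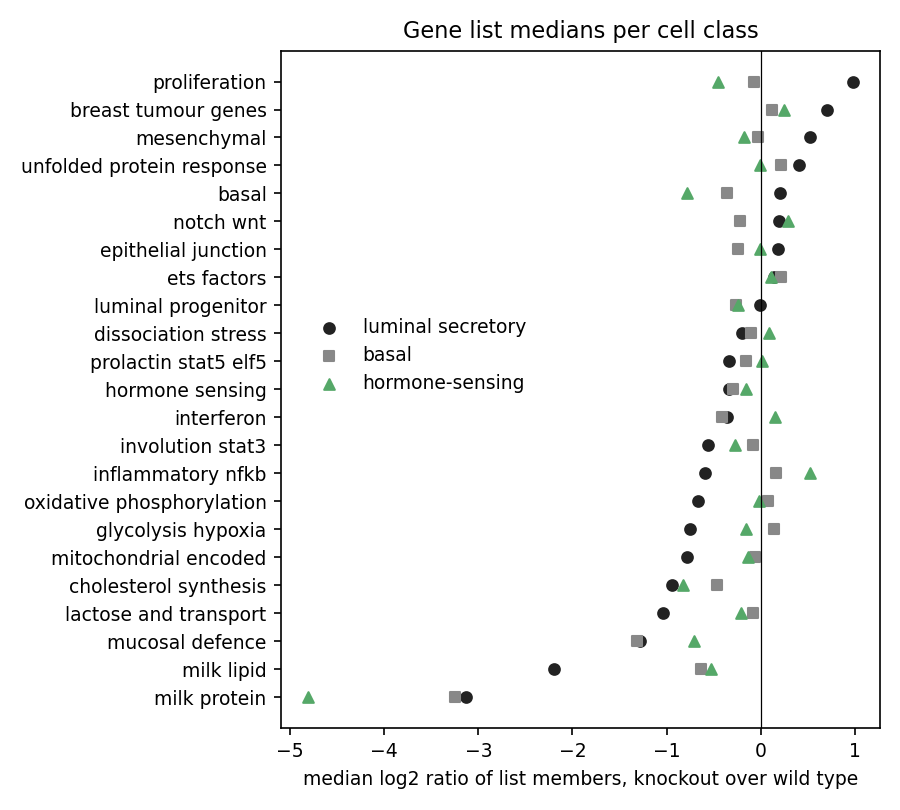
Median log2 ratio (knockout over wild type, median-ratio scaling) of the measured members of each gene list in luminal secretory, basal and hormone-sensing cells. Milk protein genes had the lowest median in each class (-3.14, -3.24 and -4.81), and proliferation the highest in luminal secretory cells (0.98); on plain scaling every luminal secretory median from -0.78 (mitochondrially encoded genes) up to 0 lies above 0.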

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

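The tests of the cluster mix within single clusters, of basal transcripts in cluster 5, of free RNA and of ribosomal copies in non-epithelial cells were chosen only after the result was seen. Thinning before summing and the comparison within clusters were added after seeing the data, with bounds for depth and for the mix over all clusters written before their results.

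Some named genes lay at least 1.5-fold higher in 1 class and at least 1.5-fold lower in another, and the difference was not tested. S100a6 was higher in knockout luminal secretory cells (1.74) and lower in basal cells (-1.58), a gap of 3.32 on the log2 scale, and the gap from basal to hormone-sensing cells was -2.33. Within luminal secretory clusters 5 and 8 S100a6 was lower (-1.89 and -1.12). Anxa2 had a gap of 2.79 from luminal secretory (1.97) to basal cells (-0.82), but within cluster 8 it was lower too (-1.50) and within cluster 5 its interval included 0 (-0.41). Lgals7 had gaps of 2.63 from luminal secretory to basal and -2.73 from basal to hormone-sensing cells. Defb1 was lower in knockout luminal secretory and higher in hormone-sensing cells, a gap of -4.80. The luminal secretory side rests on few UMIs. It had 29 UMIs in 6 of 823 knockout cells, 12 of them in 1 cell, and 100 UMIs in 57 of 2559 wild type cells. That wild type share of 2.23% was near the 2.25% of wild type basal cells. Pappa was higher in knockout basal and lower in hormone-sensing cells, a gap of 2.24, and was at 0.81 in basal cells with free RNA subtracted.

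The sort was against CD31 and CD45, yet 24 knockout and 67 wild type cells were endothelial-like and 15 and 38 were myeloid-like. A single wild type luminal secretory cell held 1116 Igkc UMIs of the 1124 in its class.

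Milk protein genes were lower in knockout luminal secretory cells. Within cluster 7 the median was -3.19 and within cluster 5 it was -0.88. A mix of clusters cannot give a difference inside 1 cluster, so the mix is not the only source in those cells. How much of the difference over the class the mix gives was not tested. In cluster 5 basal markers (0.64) and mesenchymal genes (1.48) were higher in the knockout library. Basal markers there lay at 1.91% of their level in knockout basal cells, with 0 of 113 knockout cells at the wild type doublet threshold. A different mix of states inside a cluster was not tested, and cluster 4, with 18 knockout cells, was not compared. In cluster 8, with 51.5% of the knockout cells, 5 of the 12 genes were higher and 6 lower around a median of -0.22, which decides nothing, so there and over the whole class the mix and a difference within cells cannot be told apart. The median was -2.97 after thinning every cell to 2000 UMIs. Thinning keeps each cell's expected gene shares, so it shows only that the weight of deep cells did little to the median. Whether a difference in depth plays a part otherwise cannot be decided by it. The pregnancy stage or batch of the pooled females stays open beside an effect of Ehf, since there was 1 library per genotype.

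Milk UMIs were also lower in knockout basal and hormone-sensing cells, with milk protein medians of -3.24 and -4.81. The basal median was -2.48 with free RNA subtracted, and the hormone-sensing median was -3.79 with equal weight per cell. Free RNA from luminal secretory cells is a candidate source in basal cells, since it predicts 1 basal over luminal secretory ratio for all milk genes of a library, and the larger SD of the log2 ratio over 7 genes was 0.25 in basal cells. The median ratio was 1.39% in knockout and 3.76% in wild type basal cells. In hormone-sensing cells the larger SD was 0.52, between the bounds set, and the ratios were 1.40% and 10.5%, so free RNA and other sources cannot be told apart there. Per wild type hormone-sensing cell the milk share had a median of 0.651% and a mean of 1.92%, and 4.76% of the 126 cells exceeded 10%. A few cells thus weigh heavily on the ratio of 10.5% and on the median of -4.81. The median share per wild type basal cell was 1.17%. An effect of Ehf on milk genes in basal or hormone-sensing cells was not tested.

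Among ribosomal protein genes and pseudogenes, 13 copies were picked for a like shift in all epithelial classes. The rule asked for a log2 ratio of at least 0.8 in size, in the same direction, with at least 30 UMIs in each class. Of these copies 11 were higher and 2 lower in the knockout library. The higher copies had a median of 1.02 in non-epithelial cells, and since copies were chosen for a like shift in all epithelial classes, a change confined to 1 of them could not be tested on them. Reads shared between near-identical copies and other explanations cannot be told apart, as the summed families had a median absolute log2 ratio of 0.51 against 0.58 for their copies, between the bounds set. These values cover basal cells and the 6 families with at least 2 measured copies. Rpl11 (1.22) and Rps23 (1.42), each with 1 measured copy, were left out of them. An effect of Ehf and a strain variant against the reference stay open and were not tested.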

How the results depend on the processing

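The 4 alternatives that score doublets at 1 threshold, leave out cells with basal transcripts, thin before summing or compare within clusters were chosen after seeing the data. Over the values of single genes and of lists beyond those given next, 6647 comparisons with an alternative were made, of which 5246 stayed within the counting interval, 1323 moved outside it in the same direction or without a called direction and 78 reversed. The cause was not tested unless stated. No paired analysis was possible because each genotype had 1 library. With a minimum of 200 UMIs per gene the cholesterol list of hormone-sensing cells gave no median. A minimum of 200 UMIs gave no value for 89 of the gene ratios and 8 of the list medians, and free RNA subtraction for 128 and 9, as it left no UMIs of a gene in 1 or both libraries. The clusters 5, 7 and 8 gave none for 23, 5 and 24 of the luminal secretory gene ratios, and other settings for at most 18.

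The milk protein median of luminal secretory cells was -3.14 and stayed below 0 under every alternative run. It was -2.28 on plain scaling, -2.83 on scaling outside milk genes, -3.02 with equal weight per cell, -4.09 with free RNA subtracted, -2.61 with no cell filter, -3.02 at Leiden resolution 2.0, -2.97 after thinning, -0.88 within cluster 5 and -0.22 within cluster 8. The Ehf ratio of that class was -0.51 on plain scaling, -1.06 outside milk genes, -1.21 with equal weight, -2.38 with free RNA subtracted, -1.08 with no cell filter, -1.18 after thinning and -2.11 within cluster 8. Subtraction removed a share of 5.09% in the knockout and 52.7% in the wild type library, so it acted mainly on the wild type. These shares rest on 68 and 184 non-epithelial cells, and on Csn1s2b in the knockout and Csn3 in the wild type library. Knockout Csn1s2b had 14 UMIs, in 1.47% of those cells. The profile also holds these cells' own transcripts, so values with free RNA subtracted are not a clean correction for free RNA. Scaling after subtraction also moved many genes together. In luminal secretory cells Elf5 went from -0.84 to -1.85 and Wap from -4.57 to -5.57. Oxtr went from -1.07 to -1.82 in basal cells, and Calca from 1.70 to 0.98 in hormone-sensing cells. Such moves are not effects of free RNA on single genes. The cholesterol median of hormone-sensing cells was -1.15 with free RNA subtracted.

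The luminal secretory share of knockout cells was 8.44% with no cell filter and 9.80% at Leiden resolution 2.0, where 7.71% of knockout cells lay in clusters without a name. That of wild type cells was 39.2% with the stricter filter and 23.9% with none. The median milk share per cell was 4.5% at Leiden resolution 2.0 in the knockout and 39.0% with the stricter filter in the wild type. The cycling share of knockout cells was 4.36% with no cell filter, 28.6% at Leiden resolution 2.0, 43.7% without thinning, 11.1% thinned to 1000 UMIs, 29.9% at a minimum of 2 UMIs and 10.4% at 5. That of wild type cells was 6.65% with the stricter filter, 1.27% with no filter, 17.7% without thinning, 1.99% thinned to 1000 UMIs, 9.45% at 2 UMIs and 2.40% at 5. It was below the knockout share under each alternative run. Fewer UMIs per cell, a larger milk share at a fixed depth, or a higher minimum lower this share by construction.

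On plain scaling the reversed values in luminal secretory cells, which follow from the shift of all genes, were inflammatory genes 0.27, glycolysis genes 0.11, oxidative phosphorylation genes 0.20, mitochondrial encoded genes 0.082, COX3 0.012, Elf5 0.021, Gata3 0.15, H2-K1 0.085, Ndufb9 0.0096, Rsad2 0.15 and Wfdc18 0.17. With free RNA subtracted they were breast tumour genes -0.34, Bnip3 2.97, H2-K1 2.79, Cspg4 in basal cells 3.10, Krt18 in hormone-sensing cells -0.017 and Rn18s in hormone-sensing cells 4.88, in luminal secretory cells unless stated. Breast tumour genes, from 0.70, and Krt18, from 0.69, moved by about the shift shared by many genes of their class. With called doublets kept, Krt14 was at -0.048. Within cluster 5 they were breast tumour genes -0.16, Anxa2 -0.41, Elf5 0.17, Ndufb9 0.027, S100a6 -1.89, Tnfrsf11a 0.23, Wfdc12 -1.93, Wfdc18 0.70 and Xbp1 0.12. Within cluster 8, which held 96 wild type cells, they were milk lipid genes 0.73, lactose and transport genes 0.34, cholesterol synthesis genes 0.22, oxidative phosphorylation genes 0.36, mitochondrial encoded genes 0.10, breast tumour genes -0.61, Anxa2 -1.50, Asns 1.28, Atp2c2 1.64, COX3 0.067, Clca3a2 -0.61, Col4a1 -0.27, Col4a2 -0.11, Cox5a 0.28, Cox6a1 0.25, Csn1s2a 1.52, Csn1s2b 0.78, Csn2 1.00, Csn3 1.04, Dab2 0.45, Dsp -0.62, Elf5 0.87, Elk3 -1.13, Ets1 -0.79, Fabp3 1.10, Hsd17b7 0.011, Hspb1 -1.26, Igf1r -1.51, Krt14 -0.53, Krt17 -0.32, Lao1 0.24, Lgr4 0.068, Lpl 1.10, Mcm3 -0.083, Mmp14 -1.36, Msmo1 0.39, Ndufa1 0.84, Ndufb9 0.53, Notch1 -0.34, Pfkl 0.57, Pigr 0.92, Pkp1 -1.11, Prlr 0.50, S100a6 -1.12, Tagln2 -1.09, Tnfaip2 -0.43, Tnfrsf11a 0.40, Trf 0.72, Trp53 -0.25, Wfdc18 0.18 and Xbp1 0.94. Counting intervals of the values within the cluster included 0 for 4 of 8 reversed genes in cluster 5 and 18 of 45 in cluster 8. Within cluster 7 no value reversed.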

Other observations

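Values within clusters come from a comparison added after seeing the data. Stress genes of dissociation had a list median of -0.20 in luminal secretory cells, which was 0.66 on plain scaling, -0.10 in basal and 0.09 in hormone-sensing cells. Within luminal secretory clusters 5, 7 and 8 the list's median was -0.12, -0.28 and -0.62, with 11 of 21 members lower and 0 higher in cluster 8. The heat shock protein gene Hspb1 was at 1.53 in luminal secretory cells, at 1.72 within cluster 7 and at -1.26 within cluster 8, and Dusp1, a phosphatase gene, was at -1.14. The immediate early gene Fos was at -0.84 in basal cells. The involution list had a median of -0.56 in luminal secretory cells, with 10 of 22 members lower and 1 higher, led by Sgk1 (-1.50), Igfbp5 (-1.44) and the cathepsin gene Ctsd (-1.40), but that median was 0.30 on plain scaling. Interferon genes had a median of -0.36 there, or 0.50 on plain scaling, and hormone-sensing genes -0.34, or 0.52 on plain scaling. Within clusters 5, 7 and 8 the hormone-sensing list's median was -0.61, -0.10 and 0.31. Glycolysis genes had a median of -0.75 in luminal secretory cells, oxidative phosphorylation genes -0.66 and mitochondrially encoded genes -0.78, and on plain scaling these were 0.11, 0.20 and 0.08. Within cluster 8 they were -0.02, 0.36 and 0.10, and within cluster 7 -0.73, -0.51 and -0.60. In basal cells the same lists lay at 0.14, 0.07 and -0.06. Of the marker lists of other cell types, 3 had enough measured members in basal cells, fibroblast markers at a median of -0.52, pericyte markers at -0.06 and Schwann cell markers at -0.63, and none had in luminal secretory or hormone-sensing cells. The Schwann cell median rests on 3 members and was -1.24 with free RNA subtracted.

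Junction genes went both ways in luminal secretory cells. Of 31 members 7 were higher and 4 lower, around a median of 0.18. Pkp1 (2.26) and Dsp (2.03), both of desmosomes, were higher and the claudin gene Cldn8 (-2.51) lower. With called doublets kept Dsp was at 1.28, and with free RNA subtracted Pkp1 was at 3.73 and Cldn8 at -3.56. Within cluster 8 Pkp1 (-1.11) was lower and the interval of Dsp (-0.62) included 0. Of the luminal progenitor list 4 of 15 members were higher and 5 lower. Among ETS factors, with a median of 0.14, Ets1 was at 1.90, or 1.28 with called doublets kept. Within cluster 8 it was at -0.79, with an interval that included 0. Among Notch and Wnt genes, with a median of 0.19, Nrarp (1.37) and Notch1 (1.31) were higher and Lgr4 (-1.53) lower, while within cluster 8 the intervals of Notch1 (-0.34) and Lgr4 (0.07) included 0. Within clusters 5, 7 and 8 the medians were -0.04, 0.19 and -0.22 for junction genes, 0.06, 0.26 and -0.29 for ETS factors and -0.26, 0.10 and -0.46 for Notch and Wnt genes, and with free RNA subtracted they were -0.91, -0.65 and -0.45 for these lists. The mesenchymal list had a median of 0.52, or -0.07 with called doublets kept, but 1.48, 0.01 and -0.83 within clusters 5, 7 and 8. The basal list had a median of 0.21, or -0.64 with called doublets kept and -0.064 with 1 doublet score threshold for both libraries, but 0.64, -0.48 and -0.55 within these clusters.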
